A study of Homo sapiens with 32 samples.

How the data were processed

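Total RNA (miRNeasy kit) from an APEX2 line and a control line of the human iPSC line 201B7 was labelled with Cy3 and hybridised by the authors to 32 one-colour Agilent arrays, 4 for each of 8 groups: both lines as iPSCs and as cardiomyocytes sorted for EGFP at days 7, 14 and 21. Per the labels, cells were differentiated as embryoid bodies with BMP4, activin A and bFGF, then with VEGF and the Wnt inhibitor IWP-3. The deposited scanner files hold spot intensity, background-subtracted per array by Agilent Feature Extraction 11.5.1.1, per the file headers, with no scaling between arrays. The deposited value table holds log2 values. On each array they equalled log2 of the processed signal plus a constant (r = 1 over 42405 shared probes), with medians from -3.38 to -3.08, and the table served as an alternative only.

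Control spots and spots the scanner software marks as outliers (224 to 449 of 58717 per array) were left out, and spots of a probe were averaged. No spot was saturated, 57.4 to 67.3 percent of spots per array were well above background, and the 75th percentile of the signal was 736 to 1016. Signals were log2-transformed and the 75th percentile of each array was subtracted. The files carry no gene names, so probes were named through their transcript accession in the RefSeq table supplied: 27241 of 42405 probes had 1 symbol and 15164 had none. Those without a symbol stayed in the tests but are not named. The table's genome build is newer than the one in the file headers, so no coordinates are given, and the tests of neighbouring genes used only the order of genes in the table. The brightest probe over all arrays stood for a gene, giving 34390 features, and 20471 (14849 with a symbol) well above background on all 4 arrays of at least 1 group were tested. ACTN2, one of the panel genes, had no probe by name.

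Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit on 8 group means, eBayes), with Benjamini-Hochberg adjustment over the genes tested, and an adjusted p under 0.05 made a call. The 3 stage steps average the lines, the 4 line comparisons subtract control from APEX2 at a stage, and the 3 interactions subtract the control line's step from that of the APEX2 line. Where 1 side was dim on all arrays, the fold is given as a bound from the background level. The 30 gene lists (620 members, 592 symbols, 578 with a probe, 507 tested) were tested with camera at its preset correlation of 0.01, with an estimated correlation and with fry, adjusted over 90 stage, 120 line and 90 interaction tests. The comparisons, the lists, the naming rule and most alternatives were fixed before the data were examined. The rule names, per comparison, the 8 largest rises and 8 largest falls among called genes of at least 2-fold with a symbol, above background on both sides and with no overlap between groups, up to 4 members per list and a panel of 16 pluripotency and cardiomyocyte genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

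Whether replicate numbers pair the samples was checked before any calls were compared, on residuals from the group means. Same-numbered arrays of both lines at a stage correlated at 0.252 to 0.764 across genes, all 16 of them best with their own number, and 13 of the 16 pairs shared a slide. Same-numbered arrays of a line at consecutive stages correlated at -0.163 to 0.448, 12 of 24 above 0.1. These 12 all lay among the 16 pairs between cardiomyocyte stages. Numbers were therefore taken to pair the lines within a stage and not, throughout, the stages within a line. These correlations do point to a tie between some cardiomyocyte stages. Blocks on the number were run as alternatives. The arrays came from 7 slides and 4 scan days. All iPSC arrays were scanned on day 3, so that slide and scan day were run as blocks, stage shifts were taken within slides holding both stages, and scan days 3 and 4 were fitted alone.

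The alternatives were quantile normalisation, the percentile over detected probes, normexp background correction (offset 50), the value table, no filter or a stricter filter on dim genes (above background on all 32 arrays), the mean of a gene's probes, array weights, the replicate number or the slide as a block, only the groups compared in the fit, a 2-fold threshold, each line alone and each array left out in turn. Normexp was run on the median signal because the files hold no mean signal. Scan day as a block, scan days 3 and 4 alone, a block on the number within each stage, and leaving out both day 14 arrays no. 1 or the 3 control cardiomyocyte arrays no. 1 were added after seeing the data.

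The fit was tested on simulated data with the spread of these arrays, 200 of 20471 genes changed, 50 at each fold. The simulated noise was independent between arrays, with a common spread per gene in all groups. In the real data same-numbered arrays correlate and iPSC arrays vary less, so that the shares recovered are only a rough guide. Recovered at 2-fold were 78, 80 and 66 percent in the stage steps, 48, 54, 52 and 48 percent in the line comparisons and 38, 28 and 14 percent in the interactions, and at 4-fold 94 percent or more, 82 or more and 60 or more. XIST and genes of the Y chromosome were left out of all texts and figures.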

Results

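Gene expression was measured in an APEX2 line and a control line of the human induced pluripotent stem cell (iPSC) line 201B7, as iPSCs and as EGFP-sorted cardiomyocytes at days 7, 14 and 21 of differentiation. Each of the 8 groups has n = 4 arrays, a number that limits the precision. APEX2 is an engineered peroxidase used as a genetic probe for electron microscopy. The human endonuclease gene of the same symbol is another gene, and whether the array measures the transcript of the probe was not looked into, so that the line labels were not checked by it. Nothing in the labels says that the replicates are separate cultures, so the p-values measure only the spread between these samples. There is 1 APEX2 line and 1 control line, so that the probe and the line it was put in cannot be told apart. Levels are log2 signals relative to the 75th percentile of the array, given as mean ± SD.

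The step from iPSCs to day 7 asks what distinguishes sorted cardiomyocytes from the cells they came from (8 arrays per stage, both lines). SOX2, a core regulator of pluripotency, fell by 11.35 on the log2 scale, from 4.93 ± 0.21 to background on 7 of 8 day 7 arrays. POU5F1 and NANOG, its partners, fell by 8.67 (SE 0.25) and 6.58 (SE 0.31). The atrial light chain MYL7 rose by 12.23 (SE 0.18) and the troponin TNNT2 by 9.15 (SE 0.16), from -2.01 ± 0.32 to 7.14 ± 0.43. MYH6, the myosin heavy chain of early cardiomyocytes, was below background on all iPSC arrays and rose at least 3267-fold. NKX2-5, a cardiac transcription factor, rose by 1.12 (SE 0.078), and its probe was already bright in iPSCs (5.82 ± 0.096). The mean of the cardiac transcription factor list there was -4.38 in the APEX2 line and -4.21 in the control line. Whether this probe reports NKX2-5 alone was not tested. Its small changes here, at later stages and between the lines therefore say little about the gene.

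In all, 14724 of 20471 genes changed in that step, 7306 up and 7418 down, and 7906 of them by at least 2-fold. The largest falls also took in the noncoding RNA MIAT (-8.89) and the retinoic acid carrier CRABP1 (-7.49). Among the largest rises were MYBPC3 (10.67), a myosin-binding protein, POPDC2 (9.53), a membrane protein of heart muscle, and the natriuretic peptide NPPB (8.69). In this step SOX2 at day 7 and MYH7, GATA6 (1 of 8 arrays above background each), MYBPC3 and APOA2 (2 of 8 each) in iPSCs were mostly at background, so that the sizes of their changes are not exact.

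**Figure D1:**
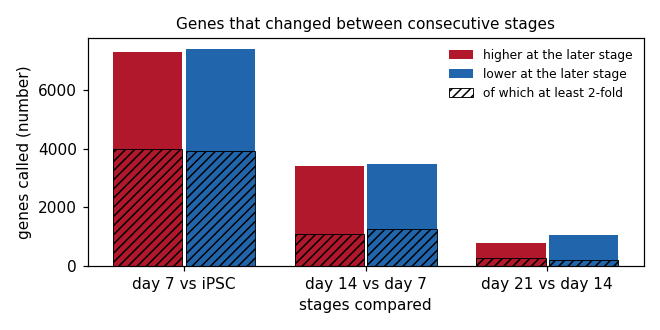
Number of genes called between consecutive stages over both lines (vertical axis), higher in red and lower in blue at the later stage, with those of at least 2-fold hatched. The counts are 7306 and 7418 at day 7 against iPSC, 3422 and 3479 at day 14 against day 7, and 797 and 1065 at day 21 against day 14.

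All 35 measured sarcomere genes rose (median 7.49, or 6.03 with dim genes at their bound; camera adjusted p = 6.14e-23, adjusted p = 0.00517 with an estimated correlation), the heavy chain MYH7 by 13.57 and the giant protein TTN by 9.04. Cardiac transcription factors rose in 18 of 20 and none fell (median 5.95, 4.57 with bounds; 7.2e-10, estimated 0.00517), with MEF2C at least 219-fold, MYOCD at least 164-fold and GATA6 by 8.45. Calcium handling rose in 16 of 19 and fell in 2 (3.96; 3.86e-07, estimated 0.00517), the exchanger SLC8A1 by 8.12 and the release channel RYR2 by 5.46. Pluripotency genes fell in 20 of 21 (median -5.44, or -4.91 with bounds; 6.22e-12, estimated 0.00517), FOXD3 at least 96.1-fold. Atrial markers rose in 8 of 10 (5.94; 1.92e-05, estimated 0.0129), and ventricular markers in 9 of 11 (3.76; 0.0001, estimated 0.0124), MYL3 at least 873-fold and MYL2 at least 6.21-fold. Natriuretic and fetal genes rose in 7 of 10 and fell in 2 (7.32, 6.36 with bounds; adjusted p = 0.00512, adjusted p = 0.315 with an estimated correlation), NPPA at least 1928-fold.

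Proliferation and metabolism moved with the sarcomere. All 28 measured G2 and M phase genes fell (median -1.89; camera adjusted p = 4.61e-08, adjusted p = 0.377 with an estimated correlation), the mitotic activator CDC20 by 2.62 on the log2 scale. S phase genes fell in 22 of 25 and rose in 1, the atypical repressor E2F8 by 2.58 (-1.63; 1.92e-05, estimated 0.377). Fatty acid oxidation rose in 20 of 25 and fell in 1 (1.13; 9.19e-05, estimated 0.0905), with the coactivator PPARGC1A up by 4.92 and ACSL1, which activates fatty acids, by 5.26. Oxidative phosphorylation rose in 33 of 46 and fell in 2 (0.35; 0.0011, estimated 0.579), the heart isoform COX6A2 by 5.95.

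Markers of other cell types were also higher in the sorted cells. Smooth muscle markers rose in 9 of 12 and fell in 2 (median 2.71; camera adjusted p = 0.00783, adjusted p = 0.315 with an estimated correlation), the actin ACTA2 by 7.66 and CNN1 by 3.65, and early cardiomyocytes also express several of these. Endoderm and liver markers rose in 13 of 18 and fell in 2 (3.59, 2.52 with bounds; 0.0222, estimated 0.703), the carrier TTR at least 424-fold, the lipoproteins APOA1 by 5.24 and APOA2 by 6.24, and the endoderm factor FOXA2 at least 31.97-fold. That median was 2.00 with slide as a block and 2.96 with scan day as a block, both of which ended the call.

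The other 17 lists gave no call at day 7. Primitive streak 5 rose and 1 fell of 9 (adjusted p = 0.138; FGF8 at least 13.96-fold), cardiac ion channels 10 and 5 of 16 (0.11; GJA1, a gap junction gene, -4.66), sinoatrial node 6 and 2 of 9 (0.131; HCN4 3.28), glycolysis 6 and 6 of 20 (0.611; ENO3 3.67, ENO2 -3.25). Antioxidant genes gave 11 up and 8 down of 28 (0.691; HMOX1 -3.49), the unfolded protein response 6 and 13 of 24 (0.6; CHAC1 -4.86), p53 targets 5 and 13 of 21 (0.0718; BAX -3.63), haem and iron 8 and 6 of 18 (0.82; FTL -1.45), interferon response 3 and 10 of 14 (0.138; IFITM1 -6.67), Wnt targets 4 and 5 of 11 (0.869; median -0.35 and mean 0.21, with opposite signs). Endothelial markers gave 6 up and 1 down of 11 (0.264; VWF 2.31), fibroblast 9 and 3 of 17 (0.301; PDGFRA 4.11, DCN -5.16), epicardial 3 and 1 of 6 (0.563), neural 2 and 6 of 10 (0.351; TUBB3 -5.94), blood 5 and 3 of 9 (0.476), skeletal muscle 4 and 1 of 9 (0.0517; CKM at least 1336-fold) and cytoskeleton 6 and 10 of 19 (0.351; TUBB2B -4.14). Adjusted over the list alone, calcium handling had 3 lower, the unfolded protein response 7 higher and cytoskeleton 11 lower, and the other counts were unchanged.

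**Figure D2:**
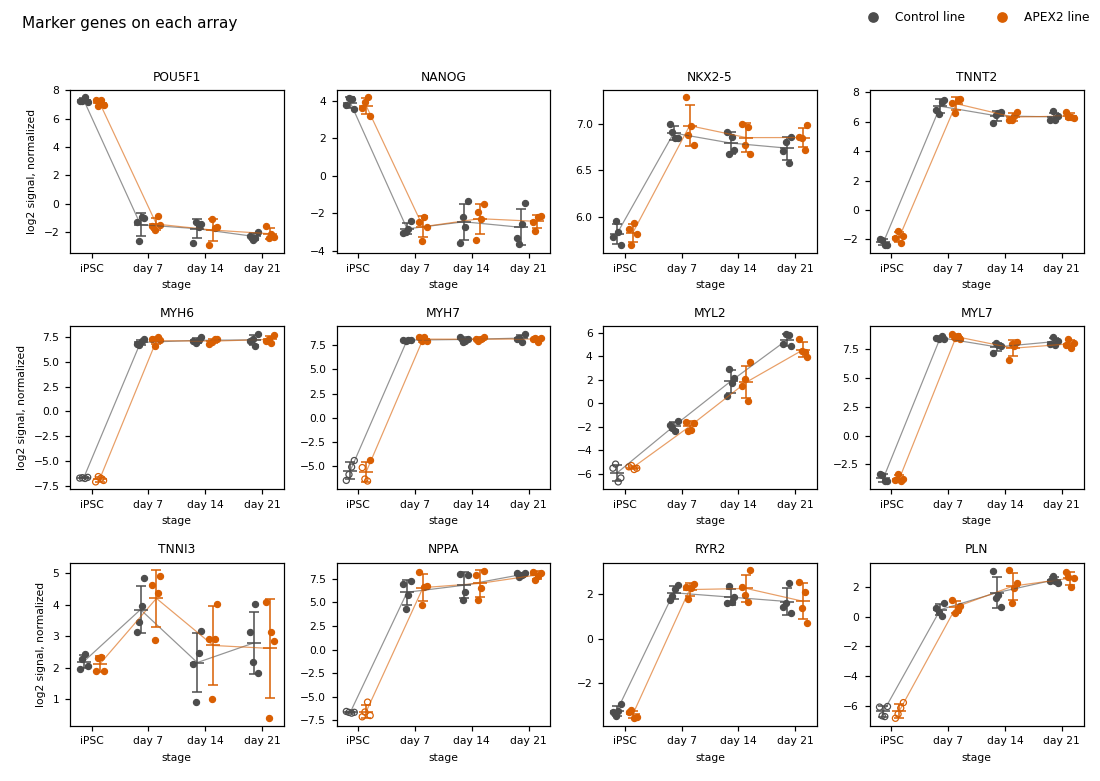
Log2 signal relative to the 75th percentile of the array (vertical axis) of 12 marker genes by stage (horizontal axis), 1 dot per array (open where not well above background), control line in grey and APEX2 line in orange, bars mean ± SD. TNNT2 goes from -2.01 in iPSCs to 7.14 at day 7, while MYL2 goes on rising to 5.00 at day 21.

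On the slide that held both stages the shifts kept their direction in 13 of 13 called lists: sarcomere 7.56, cardiac transcription factors 5.94, calcium handling 3.66, natriuretic and fetal 7.01, atrial 5.81, ventricular 3.49, fatty acid oxidation 1.03, oxidative phosphorylation 0.36, smooth muscle 2.78, endoderm and liver 3.83, pluripotency -5.07, S phase -1.51 and G2 and M phase -1.76. With slide as a block the sarcomere median was 7.11 and that of pluripotency -5.27, with scan day as a block 7.24 and -5.07, and on scan day 3 alone, the day of all iPSC arrays, 7.40 and -4.89. The count of genes was 14819 with slide as a block, 14827 with scan day as a block and 12961 on scan day 3 alone.

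From day 7 to day 14, the question is which genes move while the cells are already cardiomyocytes. MYL2, the ventricular light chain, rose by 3.80 (SE 0.35, n = 8 arrays per stage), from -1.97 ± 0.36 to 1.84 ± 1.096. LIN28A, an RNA-binding protein of early cells, fell by 4.31 (SE 0.21), from 1.14 ± 0.22 to -3.17 ± 0.65. FGF8, a growth factor of the early embryo, fell by 5.72, to background on 7 of 8 day 14 arrays. PLN, which restrains the calcium pump, rose by 1.28 (SE 0.28). TNNT2 fell by 0.78, MYL7 by 0.91, TNNI1 by 0.66 and TNNI3 by 1.59, whereas MYH6 (0.08), MYH7 (0.030), RYR2 (-0.073), NPPA (0.59), NKX2-5 (-0.12), SOX2 (0.31) and NANOG (0.40) were not called. POU5F1 (-0.36) was not called either, and its 2 probes differed in sign.

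In that step 6901 genes changed, 3422 up and 3479 down, 2350 of them by at least 2-fold. CPXM2, a secreted carboxypeptidase-like protein (6.97), VWC2, a BMP-binding protein (6.45), and MLIP, a lamin-interacting protein of the heart (5.64), led the rises. The neuropeptide NPY (-5.93) led the falls, with the lectin ITLN2 (-4.68) and the homeobox gene PRRX2 (-4.44). Sizes are not exact for genes mostly at background at 1 stage, which were FGF8 and MIXL1 at day 14 and APOC3 at day 7 (above it on 1 of 8 arrays each), VWF at day 14 and POSTN at day 7 (2 of 8 each) and ACTG2 at day 14 (3 of 8), nor for VWC2, at background on 4 of 8 day 7 arrays.

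Cell cycle genes went on falling: 27 of 28 in G2 and M phase (median -1.33; camera adjusted p = 9.7e-17, adjusted p = 0.199 with an estimated correlation), among them BIRC5 by 1.62 and MKI67 by 1.51 on the log2 scale, and 11 of 25 in S phase with 1 up (-0.51; 0.0011, estimated 0.502). Pluripotency genes fell in 12 of 21 (-0.89; 1.02e-07, estimated 0.0129), L1TD1 by 4.38 and DPPA4 by 3.15, and primitive streak genes in 6 of 9 (-1.004; 0.000699, estimated 0.0124), MIXL1 by 3.20. Ventricular markers rose in 7 of 11 and fell in 1 (1.02; 0.000739, estimated 0.0237), with the transcription factors IRX1 by 2.84 and IRX4 by 1.79 and the LIM protein FHL2 by 2.70. p53 targets rose in 9 of 21 and fell in 1 (0.47; 0.00314, estimated 0.199), SPATA18 by 2.07. The unfolded protein response rose in 9 of 24 and fell in 1 (0.25; adjusted p = 0.0275, adjusted p = 0.531 with an estimated correlation), TRIB3 by 2.06 and ASNS, which makes asparagine, by 1.60. Without the APEX2 or the control day 14 array no. 3 the median was 0.18 or 0.20 and the call ended.

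Fatty acid oxidation rose in 10 of 25 and fell in 2 (median 0.21; camera adjusted p = 0.0328, adjusted p = 0.377 with an estimated correlation), with PDK4, a brake on glucose use, up by 3.44 and CPT1A, the gate of mitochondrial import, by 1.97. The call ended without any 1 of 6 arrays: APEX2 day 7 no. 2 (0.11) and no. 3 (0.18), APEX2 day 14 no. 1 (0.17) and no. 4 (0.12), control day 7 no. 3 (0.18) and control day 14 no. 1 (0.17). Endothelial markers fell in 5 of 11 (-0.73; 0.0214, estimated 0.408), VWF by 4.17 and TEK by 2.19, and that call ended without APEX2 day 7 no. 3 (-0.69), APEX2 day 14 no. 1 (-0.67) or control day 14 no. 1 (-0.65). Cytoskeleton genes fell in 11 of 19 and rose in 3 (-0.46; 0.0227, estimated 0.405), TUBB2B by 1.95 and KRT18 by 1.19, a call that ended without either day 14 array no. 1 (-0.46 for APEX2, -0.44 for control).

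The other 20 lists gave no call at day 14, with adjusted p from 0.063 to 0.993. Members up and down were 10 and 10 of 35 in sarcomere, 1 and 6 of 20 in cardiac transcription factors (GATA6 -1.32, ISL1 -2.38), 8 and 2 of 19 in calcium handling (SLN 2.83, CAMK2B 2.19), 6 and 2 of 16 in ion channels, 1 and 1 of 10 in natriuretic and fetal genes, 3 and 3 of 10 in atrial, 3 and 1 of 9 in sinoatrial, 2 and 2 of 46 in oxidative phosphorylation and 5 and 0 of 20 in glycolysis. For the remaining lists they were 2 and 7 of 28 in antioxidant, 3 and 2 of 18 in haem and iron, 5 and 3 of 14 in interferon response, 2 and 4 of 11 in Wnt targets (SP5 -3.64), 4 and 5 of 12 in smooth muscle (MYH11 3.99, ACTG2 -2.86), 4 and 5 of 17 in fibroblast (COL1A1 -2.74, PDGFRA -3.46, POSTN 3.75), 0 and 3 of 6 in epicardial, 3 and 3 of 10 in neural, 1 and 4 of 9 in blood (KLF1 -2.33) and 5 and 3 of 9 in skeletal muscle (MYH2 4.39). Endoderm and liver markers split 6 and 6 of 18 (median 0.15), with the plasma proteins ALB up by 5.11 (SE 0.89), AHSG by 4.89, APOC3 by 5.68 and AFP by 3.62, and SOX17 down by 2.27. Adjusted over the list alone, pluripotency had 13 lower, ion channels 4 lower, natriuretic and fetal genes 1 higher and 0 lower, ventricular 9 higher, oxidative phosphorylation 1 higher and 1 lower, S phase 13 lower, unfolded protein response 10 higher, p53 targets 2 lower and endoderm 8 higher. Median, mean and test differed in sign in sinoatrial, oxidative phosphorylation, haem and iron, Wnt and neural lists, none of them called.

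Over the 3 slides holding both stages, G2 and M phase shifted by -1.87 to -1.17, pluripotency by -1.42 to -0.64, primitive streak by -1.27 to -0.31, ventricular markers by 0.51 to 2.14, S phase by -0.92 to -0.19, p53 targets by 0.26 to 0.59, endothelial by -0.87 to -0.44 and cytoskeleton by -1.02 to -0.015. Fatty acid oxidation ranged from -0.20 to 0.48 and the unfolded protein response from -0.016 to 0.58, both across 0, and MYL2 rose on each slide (2.47 to 3.32). Only slide 2 held both stages of both lines. Slide 3 gave the step for APEX2 alone and slide 6 for control alone, each from 1 array per stage, so these ranges mix lines and single arrays. On scan day 4 alone the ventricular median was 0.55 and G2 and M phase -1.21, but the calls ended for fatty acid oxidation (-0.11), S phase (-0.39), p53 targets (0.50), endothelial (-0.56) and cytoskeleton (-0.39). AFP was -0.75 there, with the sign turned. With slide as a block fatty acid oxidation was 0.067 and the endothelial call ended (-0.45). With scan day as a block p53 targets were 0.25. The 2 day 14 arrays no. 1 stood apart from the rest: without both, the calls of fatty acid oxidation (0.16), endothelial (-0.63) and cytoskeleton (-0.38) ended. The count of genes was 7005 with slide as a block, 7677 with scan day as a block and 861 on scan day 4 alone.

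**Figure D3:**
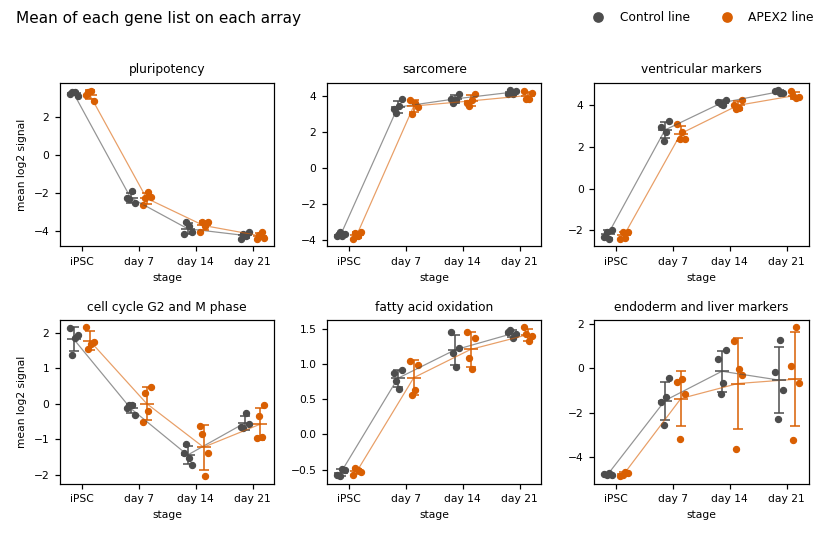
Mean log2 signal of 6 gene lists (vertical axis) by stage (horizontal axis), 1 dot per array, control line in grey and APEX2 line in orange, bars mean ± SD over 4 arrays. G2 and M phase goes from 1.82 in control iPSCs to -1.45 at day 14 and -0.55 at day 21, while the endoderm and liver arrays spread widely within each cardiomyocyte group.

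Between days 14 and 21 the question is whether the cells go on changing. MYL2 rose by 3.17 again (SE 0.35, n = 8 arrays per stage), to 5.00 ± 0.70. G2 and M phase genes turned upward, 20 of 28 rising and none falling, with the ubiquitin ligase UBE2C up by 1.13 (SE 0.18), the kinesin KIF20A by 1.18 (SE 0.26) and the spindle protein TPX2 by 1.02 (SE 0.21). CDKN2C, an inhibitor of cell cycle entry, rose by 2.54, and CDKN1A, another, by 1.41 (SE 0.34). KCNJ2, the potassium channel behind the resting potential, rose by 2.05. LIN28A fell by a further 1.86, to background on 7 of 8 day 21 arrays. KCNJ2 and CDKN2C were at background on 4 of 8 day 14 arrays, so that the sizes of these 3 changes are not exact. TNNT2 (0.0059), MYH6 (0.11), MYH7 (0.079), MYL7 (0.42), TNNI1 (-0.075), TNNI3 (0.27), NPPA (1.00), RYR2 (-0.39), PLN (0.69), NKX2-5 (-0.027), POU5F1 (-0.40), NANOG (-0.22) and SOX2 (0.072) were not called.

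The step had 1862 genes, 797 up and 1065 down, 476 of them by at least 2-fold. Complement C4B (3.19), the ATP receptor P2RX1 (3.09), the keratin KRT80 (3.10) and the stress gene NUPR1 (2.57) led the rises with MYL2. WFIKKN1, a secreted protease inhibitor (-2.53), the chromatin gene PRDM8 (-2.03), GDAP1L1 (-1.82) and SOCS2, a brake on growth hormone signals (-1.80), led the falls.

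By list, G2 and M phase had a median of 0.84 (camera adjusted p = 4.69e-20, adjusted p = 0.155 with an estimated correlation). Haem and iron genes rose in 3 of 18 (0.20; 0.00115, estimated 0.0124), the iron receptor TFRC by 1.15 and the biliverdin reductases BLVRA by 0.57 and BLVRB by 0.74. Interferon response genes rose in 5 of 14 and fell in 1 (0.29; 0.0027, estimated 0.0129), IFIT2 at least 3.40-fold, IRF9 by 0.87 and IFI35 by 0.78. Natriuretic and fetal genes rose in 2 of 10 (0.77; 0.00151, estimated 0.282), the skeletal actin ACTA1 by 1.102 and the chaperone CRYAB by 0.99. Sarcomere genes rose in 4 of 35 (0.20; 0.00172, estimated 0.377), TCAP by 1.00 and TRIM63 by 0.99. Only MYL2 rose of the 11 ventricular markers (0.63; 0.0102, estimated 0.122). The unfolded protein response rose in 2 of 24 (0.26; 0.000533, estimated 0.315), TRIB3 by 1.38 and DDIT3 by 1.20. Oxidative phosphorylation rose in 3 of 46 (0.10; 0.00115, estimated 0.579), NDUFS7 by 0.37, and fatty acid oxidation in 2 of 25 (0.14; 0.00783, estimated 0.282), the fatty acid carrier CD36 by 1.47 and FABP3 by 0.90. Cytoskeleton genes rose in 3 of 19 (0.27; adjusted p = 0.00695, adjusted p = 0.345 with an estimated correlation), SYNM by 0.98. Pluripotency genes fell in 5 of 21 (-0.27; adjusted p = 0.0109, adjusted p = 0.304 with an estimated correlation), LIN28B by 0.74 on the log2 scale.

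Smooth muscle markers rose in 2 of 12 (median 0.36; camera adjusted p = 0.0137, adjusted p = 0.352 with an estimated correlation), MYLK by 2.34 and SMTN by 0.60, but the list call ended without the day 21 array no. 2 of APEX2 (0.19) or control (0.25). The gene call of MYLK ended in 8 of 16 fits with 1 array left out (1.81 to 2.74). S phase genes rose in 2 of 25 (0.15; 0.017, estimated 0.661), RRM1 by 0.34, and the call ended without any 1 of 5 arrays: APEX2 day 21 no. 2 (0.056) and no. 3 (0.10), control day 14 no. 1 (0.053), control day 21 no. 2 (0.11) and no. 3 (0.076).

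No call was made for the other 17 lists at day 21, with adjusted p from 0.0819 to 0.921. Members up and down were 1 and 0 in primitive streak, 1 and 2 in cardiac transcription factors (MEF2C -0.71, MYOCD -0.47), 1 and 0 each in calcium handling and ion channels, 2 and 0 in antioxidant (SOD1 0.34), 2 and 2 in p53 targets (TIGAR -0.58), 1 and 1 in Wnt targets, 1 and 1 in fibroblast (PDGFRA -1.54), 2 and 2 in neural (MAP2 1.72, SOX3 -2.33) and 0 and 1 in blood. Atrial, sinoatrial, glycolysis, endothelial, epicardial, endoderm and liver (ALB 2.57, not called) and skeletal muscle lists had 0 called by limma, and adjusted over the list alone 0 except 1 higher in skeletal muscle. Adjusted over the list alone, sarcomere had 5 higher, natriuretic and fetal genes 4, oxidative phosphorylation 2, G2 and M phase 26, p53 targets 5, interferon response 6 with 2 lower, smooth muscle 3, fibroblast 2 with 3 lower, neural 4, cytoskeleton 5 and blood 3 lower. Median, mean and test differed in sign in primitive streak, atrial and skeletal muscle lists.

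Over the 3 slides holding both stages the G2 and M phase shift was 0.34 to 1.45, pluripotency -0.68 to -0.61, ventricular 0.35 to 0.42, fatty acid oxidation 0.0051 to 0.24, haem and iron 0.10 to 0.28, interferon response 0.062 to 0.20, and MYL2 0.49 to 4.04. The remaining 7 crossed 0: sarcomere -0.15 to 0.35, natriuretic and fetal -0.52 to 1.64, oxidative phosphorylation -0.24 to 0.34, S phase -0.56 to 0.56, unfolded protein response -0.029 to 0.70, smooth muscle -0.43 to 0.11 and cytoskeleton -0.20 to 0.081. Only slide 7 held both stages of both lines (MYL2 2.98). Slide 4 gave the step for APEX2 alone (MYL2 0.49) and slide 6 for control alone (4.04), each from 1 array per stage. These ranges therefore mix lines and single arrays. Slide as a block ended the calls of sarcomere (0.099), ventricular (0.31), S phase (-0.028), smooth muscle (0.15) and cytoskeleton (0.079), and scan day as a block those of S phase (0.095), smooth muscle (0.21) and cytoskeleton (0.13). With scan day as a block pluripotency was -0.44, the unfolded protein response 0.15, fatty acid oxidation 0.22, sarcomere 0.13 and ventricular 0.33. On scan day 4 alone G2 and M phase was 0.50, natriuretic and fetal 1.58, oxidative phosphorylation 0.33, fatty acid oxidation 0.27 and sarcomere 0.34, and the calls ended for pluripotency (-0.31), interferon response (0.18), the unfolded protein response (0.015) and cytoskeleton (0.14), while S phase (-0.13), smooth muscle (-0.51) and MYLK (-0.54) turned sign. Without both day 14 arrays no. 1 the calls of S phase (0.042), smooth muscle (0.27) and cytoskeleton (0.086) ended. The count of genes was 3021 with slide as a block, 2476 with scan day as a block and 161 on scan day 4 alone.

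Across the 3 steps, camera called 36 of 90 list tests. The 11 that hold with an estimated correlation were pluripotency, cardiac transcription factors, sarcomere, calcium handling, atrial and ventricular markers at day 7, pluripotency, primitive streak and ventricular markers at day 14, and haem and iron and interferon response at day 21. The fry test, which asks whether a set's genes move, on balance, one way and does not compare them with other genes, called 55.

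Line comparisons ask whether the APEX2 line differed from the control line at each stage (4 arrays against 4). GLT1D1, a glycosyltransferase-like gene, was higher in the APEX2 line at every stage, by at least 7.12-fold in iPSCs (-1.69 ± 0.43 against -6.83 ± 0.06), 13.8-fold at day 7, 7.18-fold at day 14 and 4.21-fold at day 21. It was well above background on 4 of 4 APEX2 arrays and 0 of 4 control arrays each time, and the differences of pairs on 1 slide, against a control at background, ran from 3.52 to 6.56. CT83, a cancer-testis antigen, was lower in the APEX2 line at every stage, by at least 5.34-, 3.65-, 3.74- and 3.41-fold (SE 0.56, adjusted p = 0.0017, 0.0035, 0.0004 and 0.003), and normexp background correction ended each of these calls. CUX2, a homeobox factor, was higher in the APEX2 line at day 14 by 2.10 (SE 0.27, adjusted p = 0.0002) and at day 21 by 2.43 (0.68 ± 0.15 against -1.75 ± 0.67). HDAC8, a histone deacetylase, was higher in iPSCs (0.90, SE 0.14), at day 14 (0.88) and at day 21 (0.79), and MAGED1, an adaptor of cell death signals, at day 7 (0.99) and day 21 (0.94). With 1 array left out the HDAC8 call ended in 2 of 8 fits at day 14 and 5 of 8 at day 21, and the MAGED1 call in 6 of 8 at each of its stages.

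**Figure D4:**
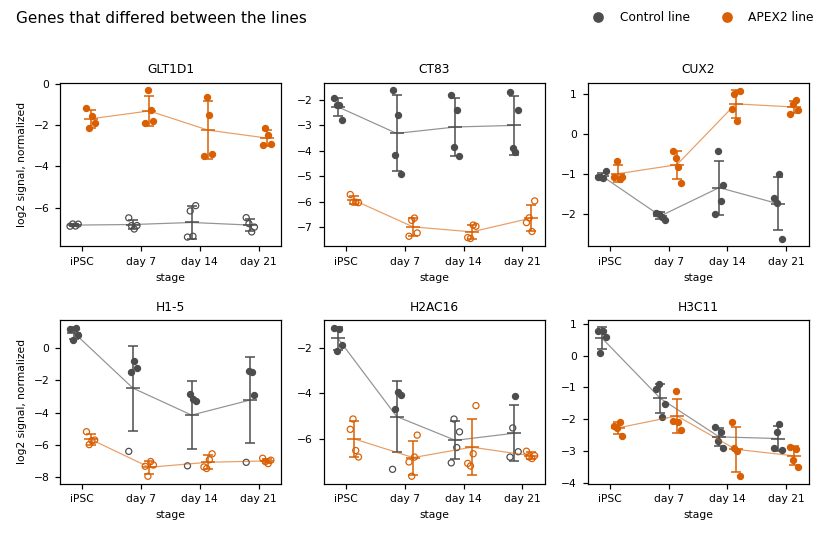
Log2 signal relative to the 75th percentile of the array (vertical axis) of 6 genes by stage (horizontal axis), 1 dot per array (open where not well above background), control line in grey and APEX2 line in orange, bars mean ± SD. GLT1D1 lies at -1.69 against -6.83 in iPSCs and apart at each later stage.

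In iPSCs 11 genes differed, 4 higher and 7 lower in the APEX2 line (283 at an unadjusted p under 0.05). This count and those of the later stages come from group means and leave out the pairing. With the pair within a stage as a block more genes were called at each stage (36, 14, 19 and 44). The replication-dependent histone genes H1-5 and H2AC16 were lower, at least 48.9-fold and 8.47-fold (SE 1.03 and 0.66), and H3C11 by -2.83 (SE 0.29). The zinc finger gene ZNF880 was lower too (-2.14, SE 0.31), and RNASE1, a secreted ribonuclease, was higher (2.13, SE 0.41, adjusted p = 0.0304), a call that ended in 7 of 8 fits with 1 array left out (1.96 to 2.34). At day 7 the count was 7, 3 higher and 4 lower (382 unadjusted), with the coiled-coil gene CCDC125 lower (-1.12, SE 0.20, adjusted p = 0.0261), which ended in 5 of 8 such fits. It was 11 without APEX2 day 7 no. 1 and 3 without control day 7 no. 3 or no. 4. Day 14 had 6, 4 higher and 2 lower (315 unadjusted), with TCL1A, a lymphoid oncogene, higher (2.26, adjusted p = 0.0475, with the control line above background on 1 of 4 arrays), which ended in 7 of 8 such fits (2.09 to 2.60). Day 21 had 10, 6 higher and 4 lower (405 unadjusted), among them S100A8, a calcium-binding protein of myeloid cells (-1.74, adjusted p = 0.0289, with APEX2 above background on 1 of 4 arrays, ended in 6 of 8 such fits), the mitochondrial ribosome gene MRPS21 (-1.12, adjusted p = 0.0302, ended in 8 of 8 such fits, -1.18 to -1.06) and CLPSL2 (at least 1.21-fold higher). It was 5 without APEX2 day 21 no. 2 or no. 4 and 6 without control day 21 no. 4. Genes named here beyond the largest changes and the lists were chosen after their values were seen. The rest of the calls were transcripts without a symbol, 1 of which was lower at all 4 stages (-0.92, -0.99, -1.03 and -1.01).

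Every one of these calls had its direction in 4 of 4 same-numbered pairs and in every pair sharing a slide. The calls were made from these same arrays, so this is no separate support against chance. With slide as a block 10 of 11, 4 of 7, 5 of 6 and 9 of 10 held, and with scan day as a block 11, 7, 5 and 10. On scan day 3 alone 10 of 11 and 6 of 10 held in iPSCs and at day 21 (2 arrays of each line at day 21), and 2 of 7 at day 7 (1 array of each line). On scan day 4 alone 0 of 7, 0 of 6 and 0 of 10 held at days 7, 14 and 21, from 1 to 3 arrays a line, though each kept its direction and GLT1D1 differed there by 5.08, 5.85 and 4.11. With only the groups compared in the fit the counts were 17, 1, 0 and 1. With the pair within a stage as a block they were 36, 14, 19 and 44, and the calls of TCL1A and of 2 transcripts without a symbol at day 7 ended. No gene of the pluripotency and cardiomyocyte panel was called between the lines: TNNT2 0.35, 0.17, -0.079 and 0.058 (SE 0.23), MYL2 0.47, -0.017, -0.060 and -0.86 (SE 0.50), POU5F1 -0.20, 0.038, -0.098 and 0.19 (SE 0.36), NKX2-5 0.011, 0.079, 0.058 and 0.11 (SE 0.11). For 80.2, 78.3, 78.3 and 77.5 percent of genes, the 95% interval of the line difference lay within 2-fold.

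None of the 30 lists had a member called between the lines at a single stage by limma, and adjusted over the list alone only skeletal muscle at day 7 had any (1 lower). Camera with its preset correlation called 15 of 120 list tests, and 0 hold with an estimated correlation (0.793 to 0.920) or by fry (0.991). The estimated correlation and fry were run on the group means, which leave out the pairing, and not with the pair as a block. Their lack of calls therefore does not show that no list shifted within pairs. The largest shifts of called lists at day 7 were natriuretic and fetal genes (median 0.50; adjusted p = 0.00365) and glycolysis (0.23; 1.56e-07), followed by cytoskeleton (0.15; 0.0432), S phase (0.14; 0.0133), G2 and M phase (0.13; 0.0432) and oxidative phosphorylation (0.076; 0.00365). On scan day 3, with 1 day 7 array of each line, 4 of these 6 had the other sign (cytoskeleton -0.12, S phase -0.092, G2 and M phase -0.16, oxidative phosphorylation -0.039). On scan day 4, also with 1 day 7 array of each line, 0 of the 6 turned direction. In iPSCs the calls were neural markers (0.38; 0.0432), p53 targets (-0.15; 0.0211) and oxidative phosphorylation (-0.031; 0.0432), at day 14 G2 and M phase (0.21; 0.000332), pluripotency (0.16; 0.0463), p53 targets (0.14; 0.0432) and skeletal muscle (-0.33; 0.0432), and at day 21 sarcomere (-0.16; 0.0203) and smooth muscle (-0.25; 0.0432). Slide as a block kept 1 of 3, 5 of 6, 2 of 4 and 1 of 2 of these, scan day as a block the same numbers, and without both day 14 arrays no. 1 none of the 4 at day 14 held. Without the 3 control cardiomyocyte arrays no. 1, 4 of 6 list calls at day 7 and 3 of 4 at day 14 ended, as did the gene calls of CCDC125 and MAGED1 at day 7 and of HDAC8 and MAGED1 at day 21. The pair within a stage as a block ended the calls of neural markers and oxidative phosphorylation in iPSCs, G2 and M phase at day 7 and pluripotency at day 14, the last of which also ended with the replicate number as a block. Leaving out a single array ended 14 of the 15 calls at least once, glycolysis at day 7 being the exception (0.20 to 0.27). At day 7 natriuretic and fetal genes then ranged from 0.14 to 0.85 and oxidative phosphorylation from -0.0028 to 0.13. The ranges at day 14 were 0.056 to 0.48 for G2 and M phase and 0.088 to 0.21 for pluripotency. For p53 targets there they were 0.11 to 0.22 and for skeletal muscle -0.44 to -0.16.

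The interaction asks whether a step differed between the lines. limma called 0 genes for the steps to day 7 and day 14 (211 and 174 at an unadjusted p under 0.05) and 1 for the step to day 21 (135 unadjusted), the haem transporter gene FLVCR2 (2.83, SE 0.46, adjusted p = 0.036), well above background on 0 of 8 day 21 arrays and 1 of 8 day 14 arrays, so that its value compares levels at background. That call ended in 13 of 16 fits with 1 array left out (2.60 to 3.17) and with slide or scan day as a block. No list had a member called. Adjusted over the list alone, the step to day 7 had 1 higher among natriuretic and fetal genes and 1 lower among neural markers. Camera called 8 of 90 list tests, none with an estimated correlation (0.713 to 0.911) or by fry. The estimated correlation and fry again left out the pairing. Glycolysis (0.34; 3.78e-08), oxidative phosphorylation (0.12; 2.83e-05), natriuretic and fetal genes (0.59; 0.000761) and G2 and M phase (0.15; 0.0441) shifted further upward, or less far down, in the APEX2 line up to day 7, and neural markers further down (-0.34; 0.0488). To day 14 neural markers were 0.83 (0.0488) and glycolysis -0.095 (0.029), and to day 21 G2 and M phase was -0.26 (0.000194), or -0.030 with no call once both day 14 arrays no. 1 were left out. On scan day 3, with 1 day 7 array of each line, the values to day 7 were 0.27 for glycolysis, -0.50 for neural markers, 0.66 for natriuretic and fetal genes, 0.021 for oxidative phosphorylation and -0.11 for G2 and M phase. The pair within a stage as a block ended the calls of FLVCR2, of G2 and M phase and neural markers to day 7 and of both lists to day 14. With slide as a block both day 14 calls ended (0.70 and -0.045), as they did with scan day as a block (0.69 and -0.046). To day 7 the call of neural markers ended with either block and that of G2 and M phase with scan day. In 16 fits with 1 array left out the calls to day 7 ended 9 times for G2 and M phase, 6 for neural markers, 1 each for natriuretic and fetal genes and oxidative phosphorylation and 0 for glycolysis. Natriuretic and fetal genes then ranged from 0.27 to 1.00 and G2 and M phase from -0.0062 to 0.35, through 0. Those to day 14 ended 7 times for neural markers (0.36 to 0.998) and 6 for glycolysis (-0.20 to -0.047), and that of G2 and M phase to day 21 ended 6 times (-0.51 to -0.037).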

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

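The tests of slide, of endoderm cells, of swapped labels, of the neighbours of H1-5 and of other splits of the arrays were chosen after the results were seen, and those of the neighbours of GLT1D1 and of an earlier or later stage before.

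GLT1D1 was higher in the APEX2 line at every stage, and the control line was at background throughout. A batch is argued against by the pairs on 1 slide, whose lowest difference was 3.52, and a gain of the region by its 10 tested neighbours, whose median difference over 16 pairs was -0.09522 (SE 0.0297). What stays open is a local event at the gene itself, such as an insertion or a silenced copy in one of the lines, and an effect of the probe, which cannot be separated with 1 line of each kind.

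Both day 14 arrays no. 1 stood apart from the other day 14 arrays, with 4087 (APEX2) and 3547 (control) genes at least 2-fold from the other replicates against 940 to 2035, and their deviations correlated at 0.764 across genes. Their slide is argued against as the whole cause by the day 7 arrays on it, which followed the deviation with a slope of at most 0.2787, and an earlier or later stage by the stage axes, which held an r squared of at most 0.05685. A condition shared by slides 1 and 2 stays open. The mean raw signal of negative control spots was 32.8 to 34.5 on these slides and 86.6 to 124.3 on the other day 14 arrays. The day 7 arrays compared with slide 2 include those of slide 1, which can lower the slope. Cells of the endoderm and liver list might contribute, although the sort for EGFP should remove them: the 2 arrays had means of 0.42 and 1.23, but another day 14 array reached 0.84, a gap of -0.4201, and the list's rule was changed after its value was seen, so that this remains undecided. A shared culture or sort behind both arrays stays open and was not tested.

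H1-5 was near the floor in the 3 control cardiomyocyte arrays no. 1 (-7.29 to -6.39), as in the APEX2 line, and higher in the other control cardiomyocyte arrays (-3.29 to -0.81), while H2AC16 was lowest in these 3 but at background in 5 of the other 9 too, and CT83 was highest in them (-1.80 to -1.60 against -4.91 to -2.38). A swap of line labels is argued against by GLT1D1, 3.001 lower in these arrays than in any APEX2 cardiomyocyte array, and a loss of the wider region by 10 neighbours, H3C11 among them, whose median deviation in these arrays was 0.04737 (SE 0.16). Slide and scan day are argued against for the day 14 and 21 arrays by the other control arrays on their slides, whose lowest H1-5 was 3.781 higher, but not for the day 7 array, whose slide and scan day hold 0 other control arrays. A loss limited to H1-5 and H2AC16 stays open, as does a culture shared over the 3 stages, and in APEX2 iPSCs H2AC16, H1-5 and H3C11, 3 adjacent tested genes, were all lower. No biological explanation beyond a loss of the wider region was tested.

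In 144 tests, each of 1 measure in 1 group, for 1 array far from its 3 fellows, 8 were found where chance gives about 1 in 20, or 7.2. They were outlier spots (224 in APEX2 day 7 no. 4 against 325 to 332, 400 in APEX2 day 21 no. 4 against 304 to 309, 449 in control day 14 no. 1 against 264 to 288), the percentage of spots well above background (63.6 in APEX2 day 21 no. 3 against 59.91 to 60.34), SOX2 (-4.3 in control day 21 no. 2 against -6.618 to -6.336), TNNT2 (6.677 in APEX2 day 21 no. 1 against 6.264 to 6.309) and TNNI1 (-4.744 in APEX2 iPSC no. 4 against -5.968 to -5.781, and -5.298 in control iPSC no. 4 against -6.198 to -6.048).

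Interaction values that were called were, up to day 7, natriuretic and fetal genes (0.5871), oxidative phosphorylation (0.1216), glycolysis (0.3442), G2 and M phase (0.1516) and neural markers (-0.3371), to day 14 glycolysis (-0.09545) and neural markers (0.8304), and to day 21 FLVCR2 (2.826) and G2 and M phase (-0.2558). FLVCR2 was above background on 1 of the 16 arrays compared, so that its value compares levels at background, and none of these lists was called with an estimated correlation.

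Among 100 splits of the arrays, the real one included, 1 gave a count as large as the real one for the step to day 7, which is the real one itself (14724 real, 5539 the highest other), and likewise 1 for day 14 (6901, 2786), so that chance can be excluded. For day 21 they were 2, the real one and 1 that called more (1862, 2298), and since the splits treat same-numbered arrays as independent, excluding chance there is less firm. For the lines the splits, which concern the counts and not any single gene, could not exclude chance: 2 of 35 splits in iPSCs (11 real, 24 the highest other), 5 of 35 at day 7 (7, 1845), 7 of 35 at day 14 (6, 490) and 5 of 35 at day 21 (10, 758). The splits calling many times the real count point to a structure of the samples, since same-numbered arrays of both lines resemble each other. Among the 8 splits that part all 4 pairs, as the real one does, the real split alone was as large at each stage (highest others 1, 2, 0 and 0), and the others differ in which number sits on which side. With 8 splits the share cannot fall under 1 in 8, so they cannot exclude chance at a single stage either. For the interactions to day 7 and 14 the real count of 0 makes every split as large by construction (100 of 100, highest other 10, and 100 of 100, highest other 1541), so that these splits say nothing, and for day 21 chance could not be excluded (30 of 100, 1 real, 1643 the highest other).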

How the results depend on the processing

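Scan day as a block, scan days 3 and 4 alone, the block on the number within a stage and the fits without the day 14 or control cardiomyocyte arrays no. 1 were added after seeing the data. Folds at a single stage of genes dim on 1 side, such as GLT1D1, CT83 and H1-5, are given as bounds, while their pair differences and the fit over all pairs are differences from the background level. Scan days 3 and 4 hold 1 day 7 array of each line and scan day 4 holds 1 APEX2 day 14 array, so that fits on them rest in part on single arrays. Of the 364 called values of named genes, 357 kept their call under quantile normalisation, 341 under normexp, 362 with the deposited table, 364 with the replicate block, 334 with the slide block, 346 with the scan day block and 310 without any 1 array. Of the 59 called lists 47, 53, 54, 58, 43, 45 and 32 did. No scaling moved the median of all genes by over 0.1.

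The counts of the steps to day 7, 14 and 21 were 7906, 2350 and 476 with a fold of at least 2. Without a filter on dim genes the step to day 7 called 21087 of 34390 features, 37.8 percent of them higher, against 49.6 percent as reported. Those to day 14 and 21 were 3309 and 154 in the control line alone and 2847 and 52 in the APEX2 line alone, from fewer arrays, and 861 and 161 on scan day 4 alone, also from fewer arrays. Fits of 1 line alone do not count same-numbered arrays of both lines as independent, so fewer arrays need not be the only reason for their lower counts. The step to day 21 gave 3021 with the slide block and 678 with its groups compared alone. The share higher in that step was 42.8 percent, and 49.1 under quantile normalisation, 49.5 under normexp, 35.9 with the scan day block, 52.2 with groups compared alone and 64.9 in the control line alone, so that its balance of rises and falls depends on the setting. For the lines in iPSCs, at day 7, 14 and 21, the stricter filter, with fewer genes, gave 5, 3, 3 and 5. The block on the number within a stage gave 36, 14, 19 and 44, and 3 and 0 for the interactions to day 7 and 21. Groups compared alone gave 17, 1, 0 and 1. Scan day 4 alone gave 1, 0 and 0 at days 7, 14 and 21. iPSC counts were 20 with the slide block, 17 with the scan day block and 41 with array weights. Day 7 counts were 4 with the slide block, 13 with the scan day block, 11 on scan day 3 alone, 4 under normexp, 12 with the replicate block and 11 without the 3 control arrays. Day 21 counts were 3 under normexp and 6 without a filter. Interactions to day 7 gave 1 under normexp, the slide block, array weights and the scan day block. The 1 gene of the interaction to day 21 was lost (0) under normexp, no filter, the stricter filter, the slide block, array weights, the scan day block, scan day 4 alone, groups compared alone and without both day 14 arrays no. 1. Counts without 1 array were 3 to 11 for the lines at day 7, 5 to 8 at day 21 and 0 to 2 for the interaction to day 21. The replicate block, an effect of each number shared by all stages, moved no other count by over 1.5 times. It does not pair the lines within each stage, as the block on the number within a stage does. It ended no call of a named gene and 1 list call, pluripotency between the lines at day 14 (0.16), and added calls of 4 named genes in the step to day 21 (ALB 2.57, ENO2 1.13, FOXA2 -1.47 and MYH8 1.59) and of 6 lists, S phase in iPSCs and endoderm and liver at day 14 between the lines, sarcomere and smooth muscle in the interaction to day 14, and natriuretic and fetal genes and endoderm and liver in that to day 21.

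Directions turned on scan day 4 alone for AFP (-0.75), endoderm and liver markers (-1.43) and fatty acid oxidation (-0.11) in the step to day 14, and for MYLK (-0.54), endoderm and liver (2.945), S phase (-0.13) and smooth muscle (-0.51) in the step to day 21. Between the lines there they turned for sarcomere at day 7 (-0.15), natriuretic and fetal genes (-0.57) and oxidative phosphorylation (-0.16) at day 14, and in the interactions for neural markers to day 14 (-0.033) and sarcomere to day 21 (0.39). Scan day 3 alone turned oxidative phosphorylation (-0.039), S phase (-0.092), G2 and M phase (-0.16) and cytoskeleton (-0.12) between the lines at day 7, G2 and M phase at day 21 (0.40), and S phase (-0.19) and G2 and M phase (-0.11) in the interaction to day 7. The mean of probes turned POU5F1 in the step to day 14 (1.12), because its 2 probes differ in sign. Without 1 array the line differences ranged from -0.049 to 0.30 for G2 and M phase at day 7, -0.069 to 0.085 for oxidative phosphorylation at day 14, and at day 21 from -0.15 to 0.18 for glycolysis, -0.28 to 0.13 for S phase, -0.25 to 0.18 for the unfolded protein response, -0.71 to 1.03 for endoderm and liver and -0.44 to 0.13 for smooth muscle. The cause was not tested where no fewer arrays or genes are named.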

Other observations

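The count of zinc finger genes and the test of the same genes at each stage were chosen after the results were seen, and the fit over all pairs before.

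A difference between the lines shared by the 4 stages may be too small for 4 pairs, so all 16 pairs were fitted together with the pair as a block: 106 genes were called, 63 higher and 43 lower in the APEX2 line (2355 at an unadjusted p under 0.05), 22 of them by at least 2-fold, against 44 in the fullest single stage with the same block. The fit counts the pairs as independent. Same-numbered arrays of a line at consecutive stages correlated at up to 0.448, so pairs of the same number at different cardiomyocyte stages may share a culture. That would make the 106 too many. The fit tests the mean over the pairs, so a gene that differs at only some stages can be called too. More pairs alone can also raise the count, so 106 against 44 does not by itself show a difference shared by all stages. GLT1D1 (4.83), CT83 (-3.80), HDAC8 (0.82), MAGED1 (0.91), CCDC125 (-0.91) and MRPS21 (-0.91) had their direction in 16 of 16 pairs, the same pairs that called them. GLT1D1, CT83 and H1-5 (-4.54) are dim in 1 line, so that their values are differences from the background level and only the direction is read. The homeobox genes CUX2 (1.47), PITX1 (1.22) and HOXC6 (0.83) were higher on average over the pairs, as were the antisense RNA SVIL-AS1 (2.64) and SLFN13 (1.29), a ribonuclease of the interferon response. CUX2 overlapped between the lines in iPSCs (-1.14 to -0.68 in APEX2, -1.10 to -0.94 in control), so that its value comes from the cardiomyocyte stages. HEY2, a transcription factor of the cardiac and ventricular lists, was lower (-0.43, adjusted p = 0.0328 by limma) and was the 1 list member called.

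Zinc finger (ZNF) genes were 11 of the 34 called lower with a symbol, among them ZNF700 (-1.76) and ZNF880 (-1.48), or 32.4 percent against 3.02 percent of the 14849 genes tested with a symbol, and 2 of the 50 called higher. The class was picked on seeing these genes, many ZNF genes lie in clusters and are not independent, and no p is therefore given. With 1 line of each kind the probe and the history of the line cannot be told apart.

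Over all genes, whether the same ones differ at each stage remained open: the line differences of 2 stages correlated across genes at 0.09414 at the lowest and 0.363 at the highest, and genes are not independent replicates. Single genes went both ways. GLT1D1 and CT83 were called at all 4 stages, whereas H3C11 was -2.83 in iPSCs and -0.55, -0.39 and -0.54 at days 7, 14 and 21.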
